A study of Mus musculus with 10 samples.

How the data were processed

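The study used a mouse model of acute myeloid leukaemia in which cells carrying the MLL-AF9 fusion gene and a GFP reporter were injected into the tail vein of CD45.1 recipient mice. Bone marrow was collected when GFP+ cells had reached 2% in peripheral blood. GFP+ leukaemia cells and GFP-negative CD11b+ myeloid cells of the bone marrow micro-environment were sorted, RNA was extracted with TRIzol, and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The treatment protocol states that both populations were sorted by flow cytometry, whereas the series design text states that the myeloid cells were selected magnetically as CD45.2-negative CD11b+ cells. The cell type field of all 10 libraries reads as leukaemia cells, so the groups were taken from the sample titles. Each group held 5 libraries. The labels do not say whether libraries came from separate mice, and p-values then measure only the spread between these libraries.

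The authors deposited 1 table of 10141 genes by 10 libraries, holding normalised variance-stabilised values on a log2 scale. HISAT2 (versions 2.0.4 and 2.2.1) and DESeq2 were named in the submitters' processing notes. The genome build, gene annotation, read counter and strand setting were not given in the sources used here, so no coordinates are given. Of the gene names, 10133 were found among the symbols of the GENCODE annotation at hand, and 4 entries carried a whole number in place of a symbol and were not named.

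All 10 libraries shared the same lowest value, 8.1823, which corresponds to 0 reads. The variance-stabilising function was inverted under the assumption of a shared parametric form, and low values then fell on whole multiples of 1 read. With a tolerance of 0.1 read and up to 300 reads, 100.0% of the low values came out whole in each library. Reads, size factors and normalised reads (reads divided by the size factor) were recovered in this way. The recovery was exact for 100.0% of the simulated values scored, which left out 0 and the highest reads. The simulated values were made with the same function, so they do not test its assumed form. Over all libraries 36 values were of 1 read and 433 were of 2 reads, and 1466 were of 4, 6, 8 or 10 reads against 1123 of 3, 5, 7 or 9. Even values would be in excess if both reads of a pair were often counted, so a read given here can be part of a counted pair. Genes outside the table are not analysed here, so the reads of a library are those of the 10141 genes and not its sequencing depth.

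The table did not hold all genes. Its order followed the difference between the groups (Spearman rho = 0.98 between position and p, across genes), and the highest unadjusted p of any gene was 0.243. Adjusted p-values therefore describe a set of genes already selected for a difference, and are not false discovery rates over the transcriptome. A stricter adjustment of the limma p-values counted each of 55450 annotated genes as a test, and treated those without an entry as not different.

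The comparison was fitted with limma (version 3.58.1, R 4.3.3) on the deposited values, leukaemia minus myeloid, with a trended prior variance, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Genes were kept where the mean over the 10 libraries lay over 1 unit above the lowest value, which corresponds to about 146 normalised reads. Log2 differences are differences of variance-stabilised means, which understate the change of genes with few reads, and the folds given are ratios of mean normalised reads. A simulated 2-fold change had a median log2 difference of 0.76 and a simulated 4-fold change one of 1.46. Tested on simulated data for this comparison over 8210 genes, the fit called 32% of 50 genes changed 1.25-fold, 78% of 50 changed 1.5-fold, 94% of 50 changed 2-fold and 98% of 50 changed 4-fold, and 5 of 8010 unchanged genes. Most simulated genes were unchanged, while 8062 of the 8079 genes tested in the data passed. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power or error rate in the data. Values are given as mean ± SD over 5 libraries.

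The test, the filter, 34 gene lists with 797 memberships, the rule for naming genes and most alternative settings were set before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The mean value of each list in each library was compared with an exact two-sided permutation test over all 252 assignments, for which 0.00794 is the smallest p. Named genes were, first, the 10 highest and the 10 lowest log2 differences among passing genes whose groups did not overlap. From each list, at most the 2 highest and 2 lowest members that passed and the most abundant member that did not were added. A fixed set of glucose, fusion-programme and sort-marker genes, and the genes a hypothesis was about, completed the rule. Wfdc21 was named after its values were seen. Genes were left out of the text for length, some genes that the rule takes are not reported here, and Gapdh and Kmt2a of the fixed set are not analysed here. The alternatives set then were other filters on low values, quantile normalisation, median centring, a replicate block, other variance estimates, array weights and leaving out each library. Added after the values were seen were a voom fit of the recovered reads, the same fit scaled to the total of the table, the adjustment over all annotated genes, and leaving out myeloid replicates 2 and 4 together. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 in R.

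No libraries were duplicates, since the lowest chi-square per degree of freedom between libraries of 1 group was 9.1. Reads of multigene families and pseudogenes could be shared in counting, and members of the ribosomal protein and Stfa families are reported as uncertain.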

Results

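RNA sequencing compared GFP+ MLL-AF9 leukaemia cells with GFP-negative CD11b+ myeloid cells from the bone marrow of leukaemic mice, with 5 libraries in each group. MLL-AF9 is a fusion of the histone methyltransferase MLL with AF9 that drives acute myeloid leukaemia, and CD11b is a surface integrin of mature myeloid cells. The series title places the comparison in a study of how glucose is divided among cells of the leukaemic bone marrow. The 10141 genes of the table held between 24099551 and 30879571 recovered reads per leukaemia library, and between 24712749 and 32247804 per myeloid library. After division by the size factors, these genes summed to 22612620 ± 216020 normalised reads in leukaemia and 35267209 ± 2566999 in myeloid cells (SD, n = 5 each). The ratio was 1.56. The secondary and tertiary granule and mature neutrophil lists together took 14.5% of myeloid and 1.0% of leukaemia normalised reads. No group of normal immature cells was analysed here. Leukaemia and maturation stage therefore cannot be told apart in this comparison, for the glucose genes as for the others.

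Sgip1, an endocytic adaptor gene, had the highest log2 difference among the named genes at 4.75, with 9691 ± 324 normalised reads in leukaemia and 27.9 ± 22.5 in myeloid cells. Myo18b (124-fold) and Ikzf2, which encodes the transcription factor Helios (64.8-fold), were also higher in leukaemia. So were Igf2bp3, an RNA-binding protein gene (304-fold), and Penk, the proenkephalin gene (45-fold). Retnlg, a resistin-like gene of neutrophils, had the lowest log2 difference at -7.64, with 226 ± 143 normalised reads in leukaemia and 134801 ± 35912 in myeloid cells. Of 8079 genes tested, 8062 passed the adjusted threshold of limma, 3965 higher and 4097 lower in leukaemia. Of these, 2234 also had an absolute log2 difference of at least 1 (769 higher and 1465 lower). The 2-fold genes were 1049 higher and 1074 lower after quantile normalisation, 1839 higher and 2012 lower with voom, and 3557 higher and 1067 lower with voom scaled to the total of the table. The groups did not overlap for 86.8% of the tested genes, against 0.794% by chance, in a table that held only genes selected for a difference. Scaled to the total of the table, 67.4% of passing genes were higher in leukaemia, against 49.2% with the authors' size factors, since this scaling raised the median log2 fold by 0.64.

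Of the tested glucose transporter genes, 3 of 4 were lower in leukaemia cells than in myeloid cells. Slc2a3, which encodes the high-affinity transporter GLUT3, was 47.2-fold lower, with 656 ± 68.2 normalised reads in leukaemia and 30929 ± 4576 in myeloid cells (SD, n = 5 each, limma log2 difference -4.74, SE 0.0938, adjusted p = 5.89e-13). Slc2a6 was 3.76-fold lower. Slc2a1, the gene of the widely expressed transporter GLUT1, was 1.56-fold lower (907 ± 84.3 against 1417 ± 218). Slc2a8 was 2.34-fold higher in leukaemia. Slc2a5, which encodes the fructose transporter GLUT5, lay below the filter, with 31.7 ± 12.3 normalised reads in leukaemia and 6 reads in all in the myeloid libraries, each of them in replicate 2. The 4 tested transporter genes had a median log2 difference of -0.98, 1 higher and 3 lower (camera adjusted p = 0.33). With no filter on low values 2 of 5 were higher and 3 lower, and the median was -0.45. It was -0.64 scaled to the total of the table. Scaled to the total of the table, the decrease of Slc2a1 was gone (log2 fold 0.01, adjusted p = 0.946), while those of Slc2a3 (-4.91) and Slc2a6 (-1.28) were still there.

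Glycolysis genes went both ways, with 8 of 21 tested members higher and 13 lower in leukaemia and a median log2 difference of -0.45 (camera adjusted p = 0.526). Pfkfb4, whose product makes the phosphofructokinase activator fructose-2,6-bisphosphate, was 11.9-fold lower in leukaemia (902 ± 143 against 10706 ± 1067 normalised reads). Slc16a3, the gene of the lactate exporter MCT4, was 4.83-fold lower. Slc16a1, the gene of the monocarboxylate transporter MCT1, was 3.96-fold higher. Tigar, a fructose-2,6-bisphosphatase gene, was 3.73-fold higher. Pfkl, a phosphofructokinase gene, was 2.28-fold higher (3744 ± 459 against 1643 ± 247). Pfkp was 1.17-fold higher. The hexokinase genes Hk1 (1.60-fold), Hk2 (1.70-fold) and Hk3 (1.33-fold), and Gpi1 (1.38-fold), Aldoa (1.38-fold), Pkm (1.65-fold) and Ldha (1.45-fold), were lower in leukaemia with the authors' size factors. Scaled to the total of the table, Hk1 (-0.03), Hk2 (-0.12) and Pkm (-0.07) no longer passed. The log2 folds of Gpi1 (0.18), Aldoa (0.18) and Ldha (0.12) were then above 0 without passing, Hk3 passed as higher (0.24), and the list had 9 members higher and 2 lower. After quantile normalisation Hk3 (0.19), Gpi1 (0.23) and Pkm (0.26) passed as higher. Relative to the median of all tested genes, the glycolysis median was -0.29 with the authors' size factors, -0.25 scaled to the total of the table and 0.06 after quantile normalisation.

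**Figure D1:**
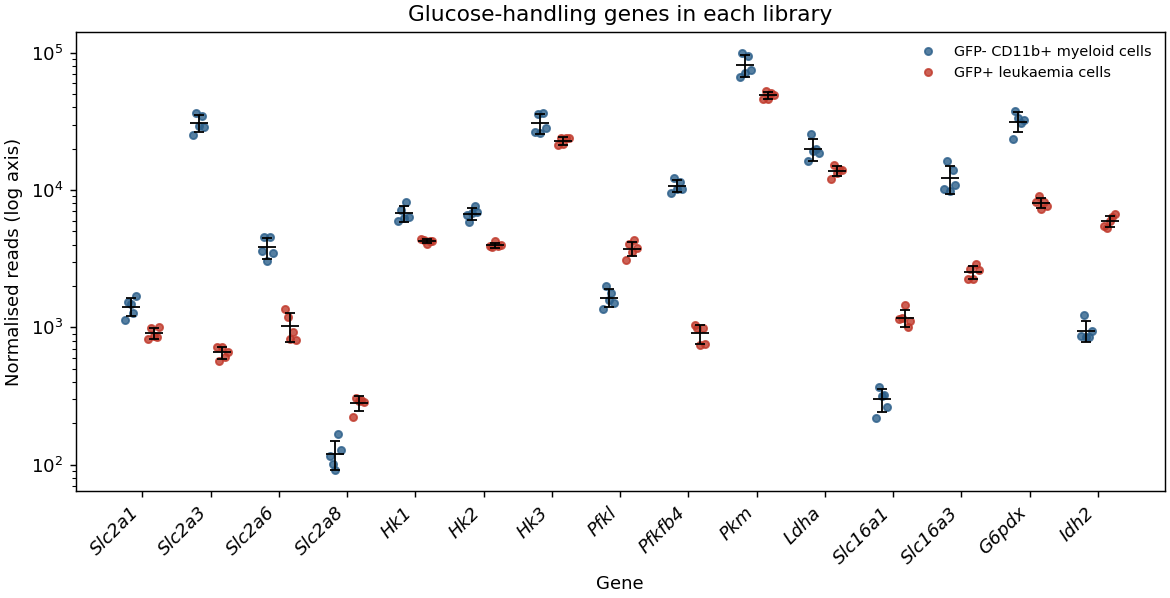
Normalised reads of 15 glucose-handling genes on a log axis, with 1 point per library, the mean as a horizontal dash and the SD as error bars (n = 5 libraries per group). The Slc2a3 points sit around 656 in leukaemia and around 30929 in myeloid cells, a gap that is still there when libraries are scaled to the total of the table, while the group means of Pkm and Ldha lie within 2-fold of each other and their differences do not pass under that scaling (Pkm passes as higher after quantile normalisation).

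Each list for a branch off glycolysis had members that went both ways. In the pentose phosphate list 2 of 7 members were higher and 5 lower (median -0.87, camera adjusted p = 0.503), and the median was -0.20 after quantile normalisation and -0.25 scaled to the total of the table. G6pdx, the entry enzyme of the pathway, was 3.92-fold lower in leukaemia (8067 ± 680 against 31596 ± 5236 normalised reads), Pgd was 1.92-fold lower and Taldo1 was 2.29-fold lower. By contrast, Prps1 and Prps2, which make the ribose precursor of nucleotides, were 3.31-fold and 2.54-fold higher. In the fructose, polyol and hexosamine list 8 of 11 were higher and 3 lower (median 0.25, camera adjusted p = 0.366), with a median of 1.04 scaled to the total of the table. Akr1b3 (2.60-fold) and Sord (2.35-fold), the enzymes of the polyol route from glucose to fructose, and Khk, the ketohexokinase gene (1.89-fold, 1789 ± 277 against 948 ± 118), were higher. Gfpt1 (3.27-fold) and Ogt (2.52-fold) of hexosamine metabolism were lower. In the glycogen list 5 of 14 were higher and 9 lower (median -0.69, camera adjusted p = 0.382), with medians of -0.40 and -0.20 under those scalings. Pygl, a glycogen phosphorylase gene, was 7.48-fold lower, Ppp1r3d was 15.1-fold lower and Phkb was 2.96-fold higher. Each of these named genes kept its direction when scaled to the total of the table.

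Tested members of the TCA cycle and oxidative phosphorylation lists, which are not specific to glucose as a fuel, were mostly higher in leukaemia. In the TCA cycle and pyruvate entry list 21 of 27 were higher and 6 lower (median 0.36, camera adjusted p = 0.0256, and adjusted p = 0.595 with an estimated correlation). Idh2 was 6.27-fold higher in leukaemia (5934 ± 586 against 947 ± 167 normalised reads) and Idh3a was 3.34-fold higher. Mpc2, a subunit of the mitochondrial pyruvate carrier, was 3.50-fold lower and Pdk3, a pyruvate dehydrogenase kinase gene, was 2.11-fold lower. In the oxidative phosphorylation list 35 of 41 were higher and 6 lower (median 0.28, camera adjusted p = 0.00557, and adjusted p = 0.721 with an estimated correlation). Of the 69 fixed members of this list, 41 had an entry. Ndufb7 (1.48-fold) and Atp5f1 (1.35-fold) were among the lower members, and both had log2 folds above 0 when scaled to the total of the table (0.08 and 0.21), where 40 members of the list were higher and 0 lower.

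In the serine and one-carbon list 17 of 18 were higher in leukaemia and 1 lower (median 1.36, camera adjusted p = 9.25e-05, and adjusted p = 0.595 with an estimated correlation). The mitochondrial hydroxymethyltransferase gene Shmt2 was 5.32-fold and the purine synthesis gene Atic 4.31-fold higher. In the fatty acid and cholesterol synthesis list 13 of 20 were higher and 7 lower (median 0.26, camera adjusted p = 0.279), with a median of 1.09 scaled to the total of the table. The fatty acid synthase gene Fasn was 6.44-fold higher (8540 ± 380 against 1325 ± 145 normalised reads) and Hmgcs1 was 2.46-fold lower. The fatty acid oxidation list had 12 of 23 higher and 11 lower (median 0.16, camera adjusted p = 0.552), and its median was -0.02 with no filter on low values and -0.21 with a stricter one. Etfb was 3.66-fold higher, and Cpt1a (2.33-fold) and Acsl1 (2.57-fold) were lower. The means of this list did not pass (exact permutation test, adjusted p = 0.151). In the glutamine and amino acid list 8 of 14 were higher and 6 lower (median 0.45, mean -0.02, camera adjusted p = 0.528). Its list means did not pass (exact permutation test, adjusted p = 0.0506). Aldh18a1 was 5.88-fold and the transporter gene Slc38a1 2.60-fold higher, and Arg2 was 142-fold and the cystine transporter gene Slc7a11 52.5-fold lower.

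The 7 tested NADPH oxidase genes were all lower in leukaemia (median -1.33, camera adjusted p = 0.00557, and adjusted p = 0.595 with an estimated correlation). Among them were Cybb (7.77-fold) and Ncf1 (5.46-fold), which encode subunits of the phagocyte enzyme. The antioxidant list had 11 of 19 higher and 8 lower, with a median of 0.30 and a mean of -0.13 (camera adjusted p = 0.548, up, while fry gave down). Gpx3 was 8.72-fold higher, Glrx 6.76-fold lower and the regulator gene Nfe2l2 3.92-fold lower. The hypoxia list had 5 of 13 higher and 8 lower (median -0.27, camera adjusted p = 0.548). Car9 was 5.28-fold higher and Bnip3l 2.96-fold lower. The median of this list was 0.33 when scaled to the total of the table. In the autophagy and lysosome list 20 of 24 were lower and 4 higher (median -0.76, camera adjusted p = 0.00557, and adjusted p = 0.595 with an estimated correlation). The median was -0.49 after quantile normalisation and -0.23 scaled to the total of the table. The lysosomal regulator genes Tfeb (5.61-fold) and Tfe3 (4.53-fold) were lower, and Atg12 was 2.06-fold higher.

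The programme associated with MLL fusions was higher in the GFP+ cells. In this list 15 of 18 tested members were higher and 3 lower (median 2.33, camera adjusted p = 0.000335, and adjusted p = 0.577 with an estimated correlation). Hoxa9 had 3237 ± 331 normalised reads in leukaemia and 16.1 ± 5.34 in myeloid cells, a 201-fold difference. Hoxa10 (217-fold) and Meis1 (38.7-fold), both developmental transcription factor genes, were also higher. Of 23 myeloid reads of Hoxa10, 17 were in replicate 5, without which the fold was 740. Id2 (5.34-fold) and Flt3 (2.72-fold) were lower. Mllt3, the gene of the fusion partner AF9, lay below the filter at 97.3 ± 12.9 and 150 ± 39.1 normalised reads. In the stem and progenitor list 9 of 12 were higher and 3 lower (median 1.02, camera adjusted p = 0.0588, from 0.0433 to 0.276 over the alternatives at the preset correlation, and adjusted p = 0.595 with an estimated correlation). With no filter on low values 10 of 16 were higher and 6 lower, and the median was 0.52. Cd34 was 25.4-fold and the stem cell factor receptor gene Kit 3.38-fold higher. The ribosome biogenesis and Myc list had 26 of 27 higher and 1 lower (median 1.62, camera adjusted p = 3.9e-08, and adjusted p = 0.595 with an estimated correlation). Myc was 9.12-fold and Wdr12 12.9-fold higher. In the cell cycle list 19 of 29 were higher and 10 lower (median 0.35, camera adjusted p = 0.162), and the median was 0.72 after quantile normalisation and 0.69 with a stricter filter, where the list passed (adjusted p from 0.0201 to 0.205 over the alternatives at the preset correlation). With an estimated correlation it had an adjusted p = 0.737. Cdk6 (10.9-fold) and the replication helicase gene Mcm2 (5.08-fold) were higher, and E2f2 (4.68-fold) and Ccnd3 (3.87-fold) were lower.

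The granule gene lists divided by the stage of granulocyte maturation at which the granules form. Primary granules form in promyelocytes. The 7 tested members of their list were all higher in leukaemia (median 2.90, camera adjusted p = 0.00916, and adjusted p = 0.595 with an estimated correlation). Ctsg was 12.8-fold higher, and Elane was 11.5-fold higher (80848 ± 8876 against 7024 ± 2544 normalised reads). Secondary and tertiary granules form later. Of 20 tested members of their list, not all of them genes of granule proteins, 19 were lower and 1 higher (median -4.63, camera adjusted p = 2.8e-07, and adjusted p = 0.595 with an estimated correlation). Ltf, the lactoferrin gene, was 100-fold lower (6719 ± 1001 against 672879 ± 86634), Mmp8 was 164-fold and Mmp9 138-fold lower. Stfa1, the higher member, belongs to a family of near-identical copies and is uncertain (log2 difference 0.53). All 25 mature neutrophil genes were lower (median -3.57, camera adjusted p = 3.9e-08, and adjusted p = 0.595 with an estimated correlation). Among them were the chemokine receptor gene Cxcr2 (134-fold), Ly6g (71.5-fold) and S100a9 (38.8-fold). The mature neutrophil list shares members with the secondary and tertiary granule list, among them Mmp9 and S100a9, so their counts are not independent. Itgam, which encodes the CD11b used to sort the myeloid cells, was 8-fold lower in leukaemia, and Ptprc, which encodes CD45, was 5.11-fold lower.

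Genes of monocytes, antigen presentation and inflammation were mostly lower in leukaemia, and differed among the myeloid libraries. In the monocyte list 17 of 18 were lower and 1 higher (median -1.77, camera adjusted p = 0.0097, and adjusted p = 0.616 with an estimated correlation). With a stricter filter on low values this list did not pass (camera adjusted p = 0.0602, from 0.000554 to 0.0602 over the alternatives at the preset correlation). The lowest member of this list was Itgam (log2 difference -2.94), which encodes the CD11b used to sort the myeloid cells. The sort therefore favoured its direction. Tgfbi was 5.36-fold lower and Plac8 3.72-fold higher. The macrophage list had 7 of 10 lower and 2 higher (median -0.80, camera adjusted p = 0.401). Apoe was 22.9-fold and the iron exporter gene Slc40a1 7.16-fold lower, and the adhesion gene Vcam1 was 3.78-fold higher. Axl did not pass (174 ± 83.8 against 718 ± 618 normalised reads, limma adjusted p = 0.0672, from 9.44e-07 to 0.627 over the alternatives), and passed without myeloid replicate 2 (0.00728) or 4 (0.017). It also passed with a replicate block (limma adjusted p = 0.0108). In the dendritic cell and MHC class II list 11 of 12 were lower and 1 higher (median -1.32, camera adjusted p = 0.0517). Cd74 was 21.2-fold (691 ± 306 against 14665 ± 12252) and H2-Aa 28.6-fold lower. Without myeloid replicates 2 and 4 this list passed camera at a median of -1.76, and over all 10 libraries it had an adjusted p = 0.684 with an estimated correlation. A replicate block also gave the list a call (camera adjusted p = 0.0299). With no filter on low values 17 of 18 were lower and 1 higher, and the list passed at the preset correlation (adjusted p = 0.00557, from 0.00212 to 0.615 over the alternatives). The monocyte list mean was 12.64 and 12.82 in myeloid replicates 2 and 4 and 13.60 to 13.81 in the other myeloid libraries. That of the macrophage list was 9.85 and 9.95 against 10.78 to 10.94. Without those 2 libraries Axl passed (log2 difference -1.45), and 7843 genes passed in all.

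In the interferon list 20 of 23 were lower and 2 higher (median -0.99, camera adjusted p = 0.00557, and adjusted p = 0.684 with an estimated correlation). The antiviral gene Oas3 was 9.40-fold lower. With the stricter filter the list did not pass (0.0689, from 0.000391 to 0.0689 over the alternatives at the preset correlation), nor did the inflammatory cytokine list (0.106, from 0.00135 to 0.106). Cxcl10 did not pass (182 ± 57.7 against 322 ± 223 normalised reads, limma adjusted p = 0.112, from 0.00422 to 0.91 over the alternatives). Without myeloid replicate 2 it passed (adjusted p = 0.0282), as it did after quantile normalisation (0.0164), with array weights (0.00422) and without myeloid replicates 2 and 4 (0.00424). Its log2 difference was -0.12 without myeloid replicate 1. In the inflammatory cytokine list 11 of 13 were lower and 1 higher (median -2.19, camera adjusted p = 0.0137, and adjusted p = 0.595 with an estimated correlation). Il1b was 89.6-fold and Ccl6 16.4-fold lower, and Tgfb1 was 1.60-fold higher. Of 15 immediate early genes, which respond to stimulation and to cell handling, 14 were lower and 0 higher (median -2.47, camera adjusted p = 0.00557, and adjusted p = 0.616 with an estimated correlation). Klf6 was 12.7-fold and Dusp1 16.3-fold lower. The heat shock gene Hspa1b did not pass (152 ± 48.6 against 587 ± 674, limma adjusted p = 0.0742, from 0.0004 to 0.582 over the alternatives). It passed without myeloid replicate 2 (0.0128) or 4 (0.0333) and with a replicate block (limma adjusted p = 0.0312). Its log2 difference went from -0.63 to -0.29 without myeloid replicate 1. The mean of this list was 11.43 and 11.23 in myeloid replicates 2 and 4 and 12.32 to 12.89 in the other myeloid libraries, and 9.74 to 10.69 in the leukaemia libraries.

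Markers of other marrow cells were few among the tested genes. The eosinophil, basophil and mast cell list had 5 of 6 lower and 1 higher (median -1.52, camera adjusted p = 0.141). With no filter on low values 13 of 14 were lower and 1 higher, and the list passed (median -0.66, camera adjusted p = 0.00537, from 0.00537 to 0.78 over the alternatives at the preset correlation). It also passed scaled to the total of the table (adjusted p = 0.0379), and had an adjusted p = 0.595 with an estimated correlation. The basophil protease gene Prss34 was 182-fold lower and Siglecf 4.39-fold higher. The T and NK cell list had 3 of 4 lower and 1 higher (median -1.28, camera adjusted p = 0.478), and Nkg7 was 4.31-fold higher. With no filter 18 of 19 were lower and 1 higher, and the list passed (median -0.78, camera adjusted p = 0.00222, from 0.00222 to 0.522 over the alternatives at the preset correlation). With an estimated correlation it had an adjusted p = 0.737. The B cell and plasma cell list had 2 of 3 lower and 1 higher (median -0.29, camera adjusted p = 0.526), and Jchain was 91.2-fold lower. With no filter 11 of 13 were lower and 2 higher (median -0.59, camera adjusted p = 0.0828, from 0.0828 to 0.731 over the alternatives), and the median was 0.32 when scaled to the total of the table. All 3 stroma and endothelium genes tested were higher in leukaemia (median 1.58, camera adjusted p = 0.0508, from 0.0344 to 0.198 over the alternatives at the preset correlation, and adjusted p = 0.595 with an estimated correlation). With no filter 4 of 5 were higher and 1 lower (median 1.41). A replicate block gave the list a call (camera adjusted p = 0.0436). Among the tested members were Pecam1 (8.98-fold) and Pdgfrb (23.2-fold, 630 ± 88.1 against 27.1 ± 21 normalised reads). A lone tested gene represented the erythroid list, Tfrc, 2.48-fold higher, and the megakaryocyte list, Itgb3, 2.14-fold lower. With no filter 2 of 8 erythroid genes were higher and 4 lower, and all 6 megakaryocyte genes were lower.

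Camera passed 14 of 32 lists at its preset correlation and 0 with an estimated correlation, where adjusted p ranged from 0.577 to 0.746. Scaling to the total of the table moved list medians by about the common shift of 0.64. They went from 0.52 with voom to 1.16 for the TCA cycle, from 0.46 to 1.11 for oxidative phosphorylation, from 0.18 to 0.81 for fatty acid oxidation, from 0.43 to 1.07 for antioxidant defence, from 0.63 to 1.27 for glutamine and amino acids and from -1.35 to -0.72 for NADPH oxidase. After quantile normalisation the medians were 0.69 for the TCA cycle and -0.70 for NADPH oxidase. Medians further from 0 with voom were -3.62 for T and NK cells, -3.36 for dendritic cells and MHC class II, -1.73 for macrophages, -4.00 for inflammatory cytokines and 3.17 for stroma. A further set test, fry, which tests whether the genes of a list move on balance 1 way and does not compare the list with other genes, passed 30. The exact permutation test of list means passed 31 of 34 lists, at adjusted p = 0.0348 or below. It did not pass fatty acid oxidation, glutamine and amino acid supply, or the erythroid list (adjusted p = 0.123). Counts of members adjusted over the list alone equalled those adjusted over all genes tested in each of the 34 lists. As the table held genes selected for a difference, the number of members that passed is not evidence for a list. The selection also favours passes of fry and of the permutation test, and makes the equal counts likely. The direction of the members carries the comparison, and covers only members with an entry. These were 23 of 30 fixed members for glycolysis, 41 of 69 for oxidative phosphorylation and 5 of 19 for stroma.

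**Figure D2:**
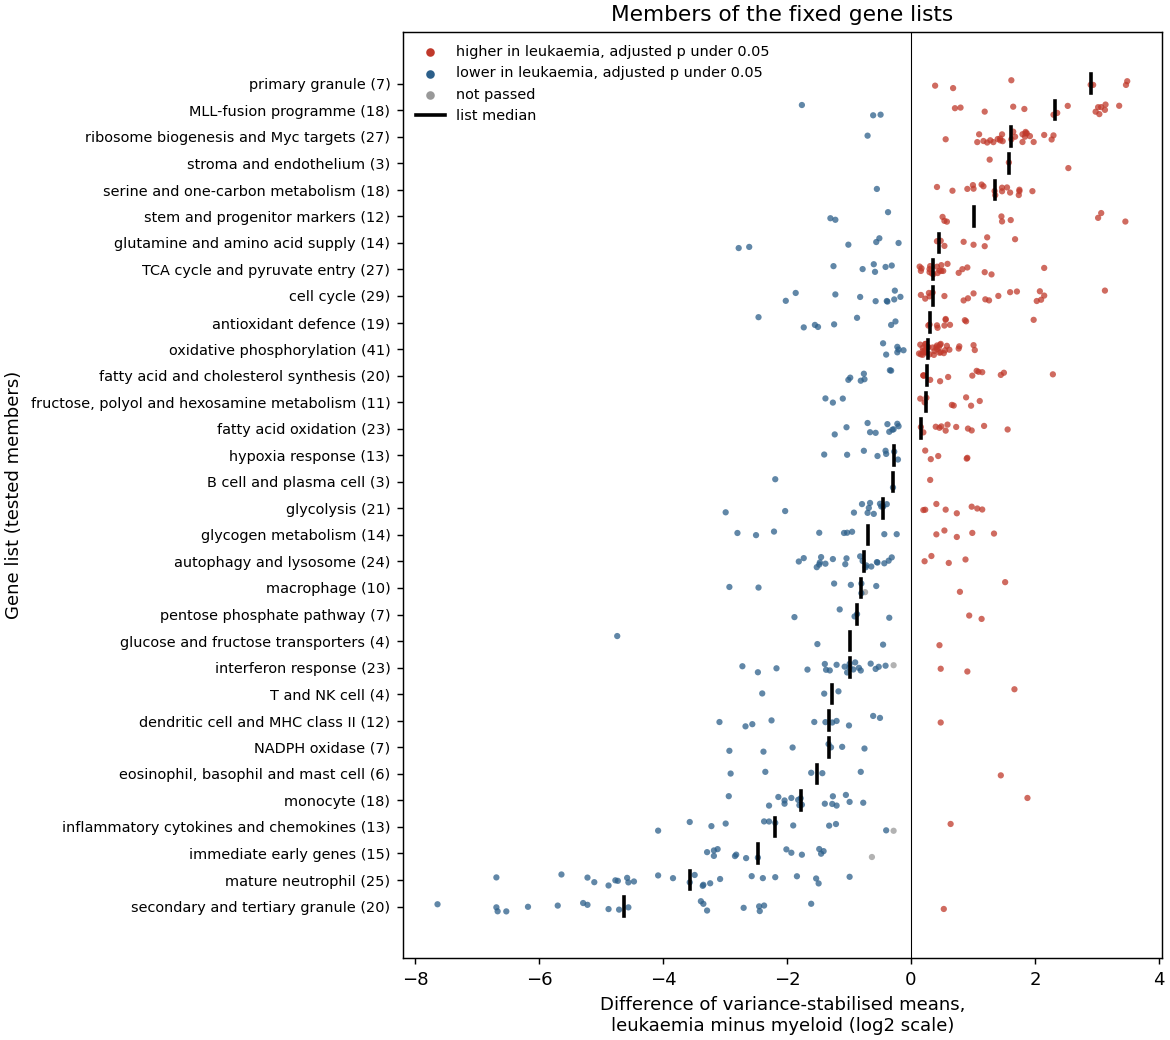
Log2 differences (leukaemia minus myeloid, variance-stabilised values) of the tested members of each list with at least 3 of them, with 1 point per gene, coloured by direction and call, and a bar at the list median. Lists run from secondary and tertiary granules at -4.63 to primary granules at 2.90, with glycolysis at -0.45 and oxidative phosphorylation at 0.28, and the glycolysis median lies above 0 when libraries are scaled to the total of the table (0.18).

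Genes of the Y chromosome were near absent from the leukaemia libraries. Eif2s3y had 6.56 ± 6.44 normalised reads in leukaemia and 3932 ± 341 in myeloid cells, and Ddx3y had 11.6 ± 9.47 and 3379 ± 715. Uty (164-fold) and Kdm5d (175-fold) were lower as well. The 4 genes summed to between 0 and 57.2 normalised reads in the leukaemia libraries and between 7815 and 11063 in the myeloid libraries, so that the leukaemia mean was 0.32% of the myeloid mean. In the other direction, myeloid levels of Hoxa9, Hoxa10 and Hoxa5 were 0.497%, 0.46% and 0.239% of the leukaemia levels. Hoxa10 was at 0.135% without myeloid replicate 5, and the 5 myeloid reads of Hoxa5 were all in replicate 1. Hoxa6 had 0 reads in the myeloid libraries and was at least 171-fold higher in leukaemia, against a floor of 3 read pairs (6 reads) over the group, which covers counting error only.

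**Figure D3:**
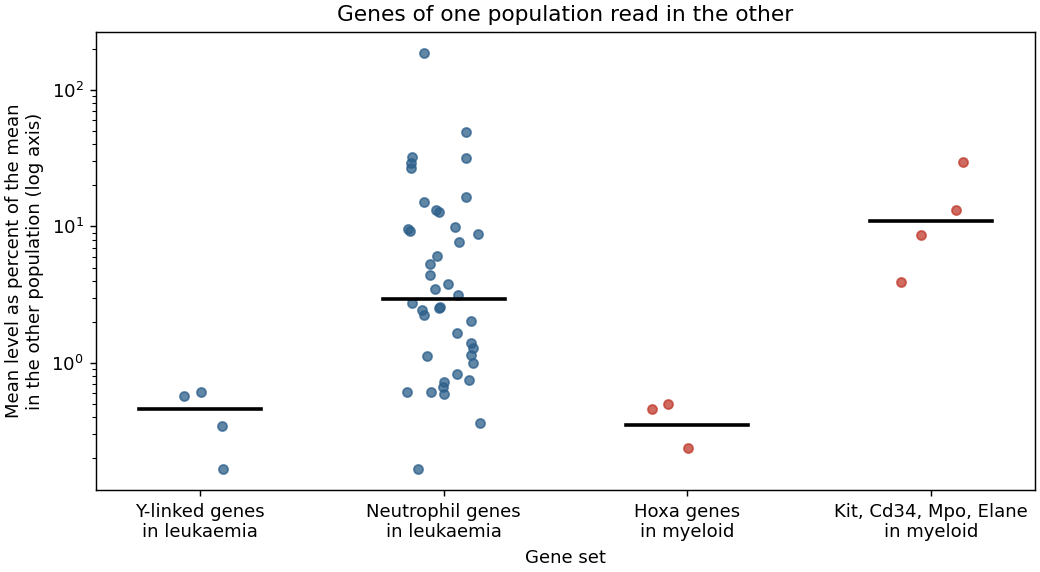
Mean level of each gene in 1 population as a percentage of its mean in the other, on a log axis, with 1 point per gene and a bar at the median of the set (Hoxa6, at 0 reads in myeloid cells, is not drawn). Y-linked genes in leukaemia lie between 0.167% and 0.608%, below the median of the 42 tested neutrophil genes at 2.94%, and the Hoxa genes in myeloid cells lie below Kit, Cd34, Mpo and Elane, whose median was 11%.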

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

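The tests of the explanations given here were chosen after the results were seen, except the comparison of X-linked genes. A library was singled out where its gap to the nearest other library of its group exceeded 0.71 of the group's range, and 20 of 320 groups of 5 did so, against about 16 by chance.

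Myeloid replicate 2 stood above the other myeloid libraries in the list means of the TCA cycle (gap ratio 0.77), oxidative phosphorylation (0.94, at 11.07 against 10.85 to 10.87), antioxidant defence (0.94) and primary granules (0.71, at 12.31 against 11.59 to 11.80). It was also the highest for Slc2a5 (1.0), Sord (0.75), Idh2 (0.75) and Etfb (0.76). Myeloid replicate 1 was lowest in the fatty acid and cholesterol synthesis mean (0.85) and highest in the eosinophil, basophil and mast cell mean (0.93), Cpt1a (0.84) and Hoxa5 (1.0, 5 reads). Myeloid replicate 3 was lowest for Myo18b (0.73) and myeloid replicate 4 highest for Nfe2l2 (0.87). Leukaemia replicate 1 was highest in the secondary and tertiary granule mean (0.89, at 11.73 against 11.60 to 11.62) and lowest for Slc2a8 (0.77). Leukaemia replicate 2 was lowest for Pecam1 (0.83) and Pdgfrb (0.84), leukaemia replicate 3 highest for Ppp1r3d (0.84), and leukaemia replicate 4 highest for Bnip3l (0.80).

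Neutrophil genes were read in the leukaemia libraries and progenitor genes in the myeloid libraries. If the leukaemia cells make no Y-linked transcripts, the Y-linked ratio of at most 0.608% bounds the host cells left in the GFP+ sort. The 42 tested neutrophil genes had a median ratio of 2.94%, over 3 times above that bound, which argues against host cells as the whole source for the set. For the 3 genes at or below it (Retnlg, Chil1 and Wfdc21) such cells and low expression cannot be told apart. The same holds for genes just above it, such as Mmp8 (0.61%), Mmp9 (0.726%) and Cxcr2 (0.746%). The bound itself rests on few reads (Uty had 4.18 ± 3.84 normalised reads in leukaemia). Leukaemia cells left in the myeloid sort are argued against in the same way, since Kit, Cd34, Mpo and Elane had a median myeloid level of 11% of leukaemia, over 3 times above the 0.497% of Hoxa9. What stays open is a host fraction richer in neutrophil than in Y-linked transcripts, and low expression of these genes by each population itself, which may account for the rest.

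The near absence of Y-linked transcripts from the leukaemia cells held in all 5 libraries. A swapped or mislabelled library is argued against, since the lowest myeloid library had 137 times the Y-linked reads of the highest leukaemia library. A female donor of the leukaemia cells is a candidate explanation, for which X genes that escape inactivation would all be higher in leukaemia. Of 3 such genes with an entry, 2 were higher (Eif2s3x 2.44-fold and Kdm5c 1.27-fold) and Ddx3x was 1.57-fold lower, a decrease that was gone when scaled to the total of the table (log2 fold -0.03). As 8062 of 8079 tested genes differed between these cell populations, the direction of so few X genes could not decide on the sex of the donor. A female donor and loss of the Y chromosome in the leukaemia cells therefore cannot be told apart here, and the labels used give no sex.

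The small decreases of glycolysis genes depended on how the groups were scaled. With voom the list median was -0.46, and 0.18 scaled to the total of the table, but this scaling raised the median of all tested genes by 0.64, so that the turn was bound to occur and decides nothing. The 44 genes of both neutrophil lists, 14.5% of myeloid and 1.0% of leukaemia normalised reads, are argued against as the only source of the unequal totals, which still differed 1.35-fold without them, but other abundant myeloid transcripts stayed in and were not tested. Relative to the median of all tested genes the list median was -0.29 with the authors' size factors and -0.25 scaled to the total of the table, but 0.06 after quantile normalisation. Scaling and a biological difference in glycolysis therefore cannot be told apart for these genes, because the table held a selected set of genes and no added standard was analysed here, while scaling to the total did not remove the decreases of Slc2a3, Pfkfb4 and Slc16a3.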

How the results depend on the processing

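Tests with voom, scaling to the total of the table, adjustment over all annotated genes and the joint removal of myeloid replicates 2 and 4 were chosen after the results were seen. The count of 8062 genes ranged from 5799 (stricter filter) to 10088 (no filter) and from 7888 to 7959 with each library left out, and was 7314 adjusted over all annotated genes. The 2-fold count of 2234 was 3851 with voom and 4624 with voom scaled to the total of the table. The voom increase goes with the scale, since variance-stabilised differences understate folds. In 1 of 100 splits of the 10 libraries, the real one, 8062 genes passed, and the highest other split gave 0. As the genes had been selected on the real split, this does not show whether chance can be excluded. Of 123 named genes, 109 kept their direction and call under all alternatives. The table holds reads of selected genes only, so depth limits genes near the filter and absolute scaling.

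Camera passed 14 lists, 0 with an estimated correlation and 30 with fry. With an estimated correlation the TCA cycle (median 0.36) and oxidative phosphorylation (0.28) lost their calls, and with fry the transporter (-0.98), glycolysis (-0.45) and pentose phosphate (-0.87) lists gained one, as fry does not compare a list with other genes. The glycolysis median turned to 0.15 after quantile normalisation and 0.18 scaled to the total of the table, that of hypoxia to 0.05 and 0.33, and that of B cells to 0.15 and 0.32. The stricter filter ended the calls of the monocyte (camera adjusted p = 0.0602), interferon (0.0689) and inflammatory cytokine (0.106) lists, which passed under the 20 other alternatives at the preset correlation. It gave a call to the cell cycle (0.0233) and stem and progenitor (0.0433) lists. At the preset correlation the dendritic cell and MHC class II list passed under 10 of 21 alternatives (adjusted p from 0.00212 to 0.615), among them leaving out leukaemia replicate 1, myeloid replicate 2 or myeloid replicate 4. The stroma list passed under 6 of 20 (0.0344 to 0.198), the stem and progenitor list under 4 of 21 (0.0433 to 0.276) and the cell cycle list under 3 of 21 (0.0201 to 0.205). With no filter the T and NK cell (0.00222) and the eosinophil, basophil and mast cell list (0.00537) gained a call, the latter also scaled to the total of the table (0.0379). Cxcl10 passed under 4 of 21 alternatives, and Axl and Hspa1b under 6 of 21 each. The stroma list passed without leukaemia replicate 1, 2 or 5 or myeloid replicate 1 or 4, and the stem and progenitor list without leukaemia or myeloid replicate 1. The fatty acid oxidation median was -0.02 with no filter and -0.21 with the stricter one. After quantile normalisation, which moved the median of all tested genes by 0.25, log2 differences turned to 0.19 for Hk3, 0.23 for Gpi1, 0.15 for Aldoa, 0.26 for Pkm, 0.08 for Ldha and 0.18 for Atp5f1. Scaled to the total of the table they were 0.01 for Slc2a1, 0.24 for Hk3, 0.18 for Gpi1 and Aldoa, 0.12 for Ldha, 0.08 for Ndufb7, 0.21 for Atp5f1 and 0.05 for Cxcl10. The turns under scaling to the total follow from its common shift of 0.64. Quantile normalisation moved these genes by more than its shift of 0.25, and the cause of its turns and of the others was not tested.

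Libraries of the 2 groups share replicate numbers, but the deviations of same-numbered libraries correlated at 0.13, 0.21, 0.28, 0.27 and -0.02, so the numbers were not taken to pair them, although 4 of 10 libraries correlated best with their own number. The immediate early list, singled out after its values were seen, ranked the 5 numbers alike in both groups. So did the interferon, inflammatory cytokine, macrophage, and B cell and plasma cell lists, while others, such as the monocyte list, did not. Shared mice are therefore not excluded, and if mice were shared, the main fit leaves out a pairing. With the replicate block 8018 genes and 16 lists passed. It gave a call to Axl (limma adjusted p = 0.0108, from 9.44e-07 to 0.627 over the alternatives), Hspa1b (0.0312, from 0.0004 to 0.582), the dendritic cell and MHC class II list (camera adjusted p = 0.0299) and the stroma list (0.0436), and changed no other call of a named gene or list. In the blocked exact sign-flip test of list means 0 passed, and its smallest p is 0.0625.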

Other observations

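The families described here were chosen after the values were seen. Genes with a symbol of Rpl or Rps and a number, the form of most cytoplasmic ribosomal protein genes, were mostly higher in leukaemia. Of 82 tested members 76 were higher and 6 lower, with a median log2 difference of 1.12. Scaled to the total of the table, 78 of the 82 lay above 0. Symbols of this form can also name other genes, such as kinase genes named after a ribosomal protein. The counts are therefore not of ribosomal protein genes alone. Many of these genes have pseudogene copies, so single members are uncertain. All 13 tested genes encoded by the mitochondrial genome were higher in leukaemia (median 0.62, and 1.27 scaled to the total of the table).

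The myeloid libraries did not all deviate alike from their mean. Deviations of myeloid replicates 2 and 4 correlated across genes at 0.40 with each other and at -0.54 to -0.65 with those of the other myeloid libraries, where genes are not independent replicates. The other myeloid libraries correlated at 0.21 to 0.49 among themselves. All deviations were taken from the mean of these same libraries, so negative correlations arise in part by construction. In the immediate early list, leukaemia replicates 2 and 4 had the lowest means of their group as well, at 9.80 and 9.74 against 10.10 to 10.69. The 10 most abundant genes took 11.5% to 14.5% of normalised reads in the myeloid libraries and 5.4% to 5.6% in the leukaemia libraries.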
